A study of Sus scrofa with 8 samples.

How the data were processed

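Single-cell RNA sequencing was carried out on unsorted cells of abdominal adhesion tissue from minipigs. Per the labels, 4 samples came from animals given a hydrogel loaded with T-5224, a small molecule that inhibits the transcription factor AP-1, after laparotomy, and 4 control samples came from animals given saline irrigation, the surgical standard of care. No sample had the hydrogel without T-5224, so differences named T-5224 here are those of drug and hydrogel together. Tissue was minced and digested for 40 min in 1 mg/mL collagenase, and libraries were made with a droplet kit that reads the 3' end of transcripts, per the labels' protocols. The labels do not state that the samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

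The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, made with Cell Ranger 7.1.0 per the file headers. The submitters' processing notes also name Seurat 5.0.1 and the genome build Sscrofa11.1. The annotation release and the handling of intronic reads are not given in the sources used here. Every deposited barcode held at least 500 UMIs. The same 35670 features were listed in every sample, of which 17640 had a symbol in the files, 119 were named through the reference table of gene names, and 17911 had none. Total counts ran from 77358925 to 145205819 UMIs per library over 63867 barcodes in all.

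Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were called with Scrublet in scanpy 1.11.5 in each sample. In T-5224 replicate 3 and control replicate 2 its automatic threshold marked 0 barcodes, under the 0.5% set as the lowest share accepted, and the top 7.73% and 8.12% of barcodes by score were removed there, at 0.8% per 1000 barcodes. Elsewhere the automatic threshold removed 0.701% to 1.68%. The 52488 cells left were scaled to 10000 counts, logged with a pseudocount of 1 and clustered on 2000 variable genes, 30 principal components and 20 nearest neighbours (Leiden, resolution 1), without integration across samples. Genes of the AP-1, immediate-early, heat shock, mitochondrial, haemoglobin and ribosomal lists took no part in the clustering.

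A cluster was named after the class with most markers at least 2-fold over the median cluster in at least 10% of its cells, with at least 3 such markers, and is called X-like. Of 33 clusters 25 were named. The other 8, with 4921 cells, stayed unnamed because their leading genes or a second set of markers pointed to another class, and they entered only the sums over all cells. Cells of the unnamed clusters included dividing fibroblasts, neutrophils with macrophage genes, and cells with endothelial and mural genes together, by their leading genes. In 8 clusters the mean ribosomal share of UMIs per cell was under 3%, and these are called low-ribosomal clusters. Whether they hold nuclei, damaged cells or another state could not be checked without reads.

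Counts were summed per sample and class, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM normalization, its low-count filter and Benjamini-Hochberg adjustment at 0.05. A sample entered with at least 20 cells of a class, which all 8 samples had in the 6 classes tested. Log2 fold changes are T-5224 minus control, with standard errors. Levels are CPM, counts scaled to library sizes adjusted by TMM, with their SD. The difference of the treatment effect between fibroblast-like and macrophage-like cells was tested as an interaction with sample as a block. Shares of cells were compared with a two-sided exact permutation test over 70 arrangements, which cannot give a p below 0.0286, adjusted over 10 classes.

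There were 26 gene lists and 17 lists of cell type markers, fixed with the tests and the alternatives before the data were examined. A list needed 3 tested members. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. No gene list passed at 0.05 with an estimated correlation or with fry in any comparison. A list score is the mean over members of log2 CPM with a prior count of 2, each gene centred on its mean over the libraries. Members with no feature of that symbol were left out, among them JUND, MMP10, TIMP2, IL1B, IL1RN, MKI67 and HSPA1A. GZMA was left out because 2 features carry the symbol. The ribosomal list was taken by symbol and also holds RPS19BP1, RPL7L1, RPS27L and RPL26L1, which are relatives or a binding partner of ribosomal proteins. How the authors' counting treated reads shared by near-identical copies is not given, so values of ribosomal, CCL3L1, MX, OAS and IFIT genes are uncertain in that respect.

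The text names, per comparison, up to 10 genes per direction that pass, otherwise the 5 with the smallest p per direction and a symbol. Of the genes under this rule 1 is not reported here. It also names the JUN and FOS family in all cells and in fibroblast-like cells, and for each list described the 2 members with the smallest p. Genes named under other settings were chosen after their values were seen.

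Tests were tried on simulated counts with the real means and library sizes, with 200 genes changed. Over the 22558 genes of all cells, edgeR recovered 12% of 2-fold and 74% of 4-fold changes with 3 false calls among 89. The shares recovered were 14% and 76% in fibroblast-like, 44% and 86% in macrophage-like, 19% and 85% in endothelial-like, 33% and 84% in T/NK-like, 20% and 85% in mural-like and 13% and 80% in mesothelial-like cells, and 15% and 62% for the interaction. With no gene changed, edgeR made 1 call in T/NK-like cells and 0 in the other 6 comparisons, and DESeq2 1.42.0 called 17 genes in all cells and 6 in macrophage-like cells. With genes changed, false calls of edgeR were 2 of 92 in fibroblast-like, 13 of 143 in macrophage-like, 10 of 114 in endothelial-like, 8 of 125 in T/NK-like, 8 of 113 in mural-like and 4 of 97 in mesothelial-like cells, and 5 of 82 for the interaction. Those of DESeq2 were 54 of 181 over all cells and 39 of 192 in macrophage-like cells. Fry and both forms of camera found a list lowered 2-fold in all 7 comparisons. Lists of correlated genes were not tried. Camera also called unchanged lists, 2 in fibroblast-like and 1 each in macrophage-like, T/NK-like and mesothelial-like cells, against 0 with an estimated correlation.

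The alternatives were size factors from DESeq2 within edgeR, the DESeq2 test, no low-count filter and a stricter one, the replicate number as a block, each library left out in turn, no doublet removal, no cell filter and a stricter one, the same weight for every cell or class, Leiden resolutions of 0.5 and 2, classes by the highest cell score, at least 50 cells per sample, and shares as centred log-ratios or within immune and non-immune cells. Another 3 were chosen after seeing the data, namely doublets at the same expected rate in every sample, leaving out low-ribosomal clusters, and the share of cells in such clusters as a covariate.

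In the closing section, a difference left without some cells or a library was read against 50% of the full one, 1 standard error away on either side. The standard error was brought in after these values were seen, at first on 1 side only, which had taken 2 explanations as fitting that are now left open (interferon in fibroblast-like cells without control replicate 2, epithelial genes without mesothelial-like cells).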

Results

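Gene expression was measured in single cells of adhesion tissue, scar-like bands between abdominal surfaces, from minipigs given T-5224-hydrogel or saline after laparotomy, with 4 samples per group. The series title names JUN, a subunit of AP-1, as the target of the treatment. T-5224 libraries held 119350000 ± 23664000 UMIs (SD, n = 4) and control libraries 88638000 ± 11227000, a difference of 30711000 (exact permutation p = 0.0857). T-5224 replicate 2 lost 26.7% of its barcodes at the cell filter, against 8.36% to 10.3% in the other T-5224 libraries and 10.2% to 19.0% in the controls. Low-ribosomal clusters held 42.1%, 25.0%, 25.2% and 18.7% of cells in the T-5224 libraries and 44.6%, 61.6%, 31.5% and 12.7% in the controls. Control replicate 2 also had the highest median mitochondrial share of UMIs per cell, 7.27% against 2.91% to 4.55% in the other libraries, and the lowest median depth, 5277 UMIs per cell against 8393 to 17744.

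Fibroblast-like cells, which make collagen matrix, formed the most abundant class, with 63.3 ± 6.37% of cells (SD, n = 4) in T-5224 samples and 55.2 ± 4.33% in controls. The difference of 8.14 points did not pass (exact permutation p = 0.114, adjusted p = 0.476). Mesothelial-like cells, the lining of the abdominal cavity, made up 1.47 ± 0.783% of cells in T-5224 and 3.84 ± 0.913% in control samples. Each T-5224 sample lay below each control (exact permutation p = 0.0286, the smallest these 4 against 4 samples can give, adjusted p = 0.286). Macrophage-like cells made up 15.4 ± 3.14% and 15.7 ± 4.59% (exact permutation p = 0.914), and T/NK-like lymphocytes 5.25 ± 2.69% and 7.12 ± 2.31% (exact permutation p = 0.429). Endothelial-like cells made up 0.598 ± 0.253% in T-5224 and 2.08 ± 2.66% in controls (exact permutation p = 0.143), and mural-like cells, the contractile cells around vessels, 1.45 ± 0.598% and 3.14 ± 4.36% (exact permutation p = 0.886). Control replicate 2 stood apart (6.07% and 9.63%). Without it the mural-like difference turned from -1.69 to 0.479 points and the endothelial-like difference shrank from -1.48 to -0.157 points. The T/NK-like difference of -1.88 points came to -3.18 without T-5224 replicate 1 and -1.13 without T-5224 replicate 4. Dendritic-like cells made up 1.18% and 1.31%, lymphatic endothelial-like 0.484% and 0.867%, mast-like 0.639% and 0.736%, B/plasma-like 0.504% and 0.549%, and unnamed clusters 9.73% and 9.48%. The lymphatic endothelial-like difference of -0.382 points shrank to -0.0990 without control replicate 2 and came to -0.652 without T-5224 replicate 1. No class passed after adjustment. The macrophage-like difference of -0.326 points turned to 0.775 without control replicate 4. Those of dendritic-like, mast-like and B/plasma-like cells also turned without control replicate 3 (0.180), T-5224 replicate 4 (0.0552) and control replicate 1 (0.0928).

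**Figure D1:**
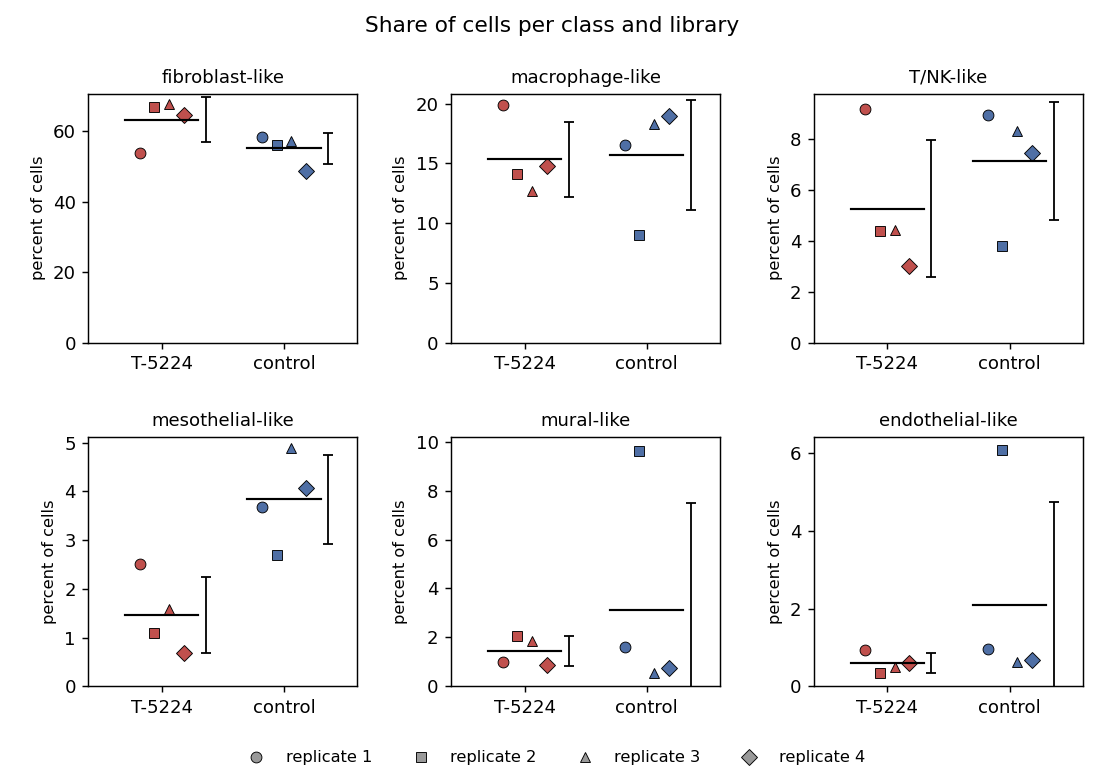
Share of each cell class (percent of cells passing filters) in the 4 T-5224 and 4 control samples, with a point per sample, the mean and 1 SD. Bars are clipped at 0 for mural-like and endothelial-like cells of the controls. Control replicate 2 lies apart at 9.63% mural-like cells.

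The level of JUN mRNA was similar in both groups within the spread between samples. JUN lies on chromosome 6 of Sscrofa11.1 at 153686425 to 153687635 (ENSSSCG00000031912). Over all cells it stood at 761 ± 342 CPM in T-5224 and 805 ± 143 CPM in control samples (SD, n = 4), a log2 fold change of -0.08 ± 0.32 (SE; edgeR adjusted p = 0.946). In fibroblast-like cells it stood at 776 ± 382 and 803 ± 182 CPM, a change of -0.05 ± 0.36 (edgeR adjusted p = 0.977). T-5224 acts on the AP-1 protein, so JUN mRNA does not check the treatment. The JUN change turned to 0.13 over all cells and 0.22 in fibroblast-like cells without T-5224 replicate 2, to 0.0097 and 0.10 without control replicate 3, and to -0.36 in both without T-5224 replicate 3. Of its partners over all cells, FOS changed by -0.11 ± 0.33, FOSB by -0.27 ± 0.43, JUNB by -0.23 ± 0.32, FOSL1 by -0.34 ± 0.30 and FOSL2 by -0.43 ± 0.22, and none passed (edgeR adjusted p from 0.734 to 0.946 with JUN). Without T-5224 replicate 2 FOS, FOSB and JUNB came to 0.14, 0.01 and 0.01. With the replicate block JUN, JUNB, FOS and FOSB came to -0.18, -0.36, -0.23 and -0.49, without low-ribosomal clusters JUN, JUNB and FOS to -0.16, -0.38 and -0.22, and with their share as a covariate JUN and FOSL1 to -0.16 and -0.22. With the same weight for every cell JUN, FOS and FOSB came to -0.14, -0.17 and -0.60, and for every class JUN, JUNB and FOSB to -0.13, -0.13 and -0.58.

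**Figure D2:**
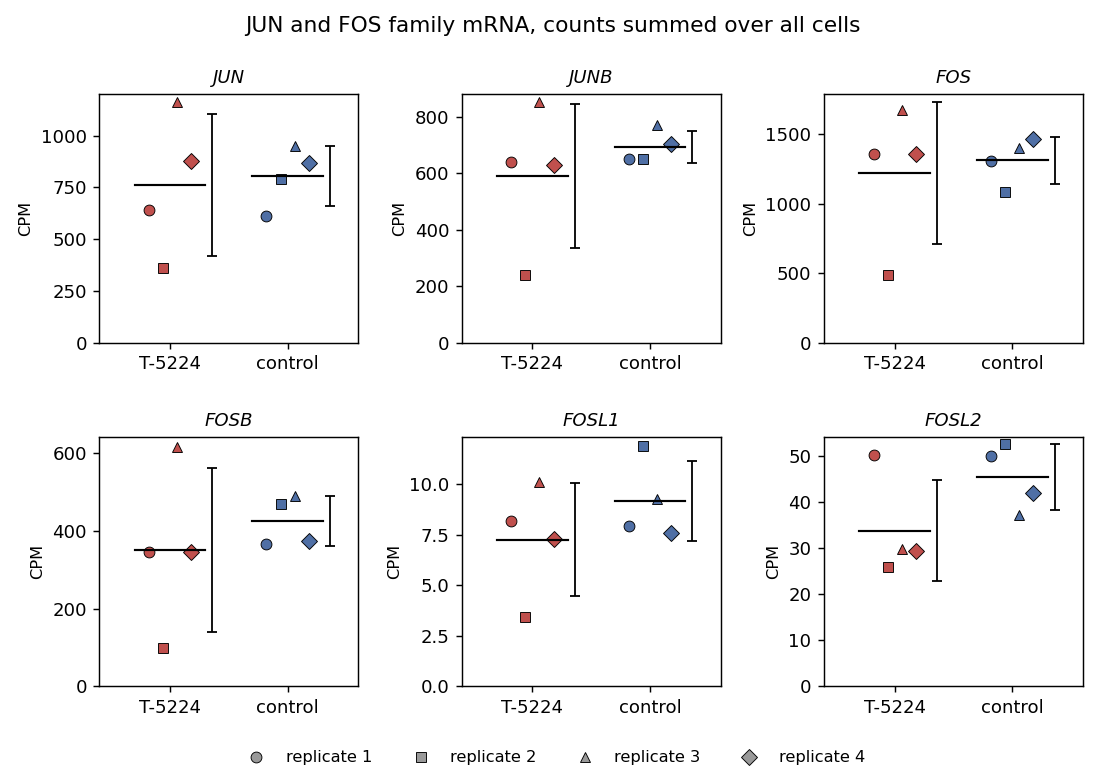
Levels of JUN, JUNB, FOS, FOSB, FOSL1 and FOSL2 in CPM over all cells of the 4 T-5224 and 4 control samples, a point per sample with the mean and 1 SD. JUN averages 761 and 805 CPM over all cells.

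Over all cells, groups of genes of the interferon response, inflammatory signalling and vessels lay lower in T-5224 samples, and genes of cell division lay higher, while no single gene passed in edgeR. The interferon response list fell as a group, with 19 of 21 members lower, a median log2 change of -0.81 and a camera adjusted p of 4.7e-11. Its members with the smallest p were IFIT2, at 4.81 ± 1.04 CPM against 13.7 ± 7.11 (SD, n = 4; -1.51 ± 0.42, SE), and RSAD2 (-2.35 ± 0.70). The inflammatory cytokine list had 14 of 14 members lower (median -0.65, camera adjusted p = 0.000127), among them LIF (-1.18 ± 0.44), and CCL2 (-0.84 ± 0.40). The angiogenesis list had 14 of 14 members lower (median -0.71, camera adjusted p = 2.18e-05), with TEK at -0.78 ± 0.21 and DLL4 at -1.61 ± 0.75. The immediate-early and dissociation list, genes that tissue handling also induces, had 20 of 21 members lower (median -0.31, camera adjusted p = 2.18e-05), with EGR3 at -0.70 ± 0.38 and IER5 at -0.56 ± 0.31. Of 11 AP-1 subunits 10 were lower (median -0.23), and the list did not pass (camera adjusted p = 0.055), with JDP2 at -0.29 ± 0.20. The proliferation list rose with 16 of 17 members higher (median 0.35, camera adjusted p = 2.18e-05), including TYMS (0.55 ± 0.22), and BIRC5 (0.56 ± 0.22). Ribosomal protein genes rose with 64 of 69 higher (median 0.26, camera adjusted p = 5.63e-09), led by RPS19BP1 (0.44 ± 0.19) and RPL7L1 (0.36 ± 0.19). With an estimated correlation these 7 lists had adjusted p = 0.628, and 0 members passed over all genes in edgeR and 0 adjusted over the list alone.

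The list scores over all cells showed libraries apart from the rest. T-5224 replicate 2 had the lowest immediate-early score, -1.24 against 0.01 to 0.28 in the other 7 libraries, and the lowest cytokine score, -1.53. Control replicate 2 had the highest interferon score, 1.05, and the highest angiogenesis score, 1.6, along with the highest endothelial-like and mural-like shares, the highest mitochondrial share and the lowest depth. Without T-5224 replicate 2 the immediate-early median came to -0.08 (camera adjusted p = 0.149) and that of the cytokines to -0.38 (0.0762), the AP-1 median to -0.03, and 5 lists passed in place of 9. Without control replicate 2 the angiogenesis median came to -0.11 (0.159) and that of interferon, which kept its call, to -0.40. DLL4 came to -0.081, RSAD2 to -1.13 and CCL2 to -0.46 without that library, and EGR3, IER5 and JDP2 to -0.47, -0.33 and -0.14 without T-5224 replicate 2. Without control replicate 4 the cytokine median came to -0.21 (0.124). The AP-1 list passed without T-5224 replicate 1 (-0.31, 0.0303), 3 (-0.36, 0.00347) or 4 (-0.28) or control replicate 1 (-0.33). Medians that moved by over 1.5 times and kept their call were those of immediate-early genes without T-5224 replicate 1 (-0.49) or 3 (-0.51), proliferation without T-5224 replicate 4 (0.20), and ribosomal genes without control replicate 1 (0.14) or 2 (0.17). AP-1 subunits also passed with a stricter low-count filter (-0.24, 0.0475) or cell filter (-0.27, 0.0347), with the replicate block (-0.32, 0.0284), where immediate-early genes came to -0.47, and without low-ribosomal clusters (-0.27, 0.0211), where ribosomal genes came to 0.11 and proliferation to 0.16. With the low-ribosomal share as a covariate, chosen like that setting after seeing the data, interferon came to -0.40, ribosomal genes to 0.13, RSAD2 to -1.31, DLL4 to -0.55 and EGR3 to -0.47. With the same weight for every cell IFIT2, RSAD2 and DLL4 came to -1.0, -1.21 and -0.85, and DLL4 to -0.77 with the block. With the same weight for every class RSAD2 came to -0.95, DLL4 to -0.46, LIF to -0.77, CCL2 to -0.52, TEK to -0.41 and EGR3 to -0.40.

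**Figure D3:**
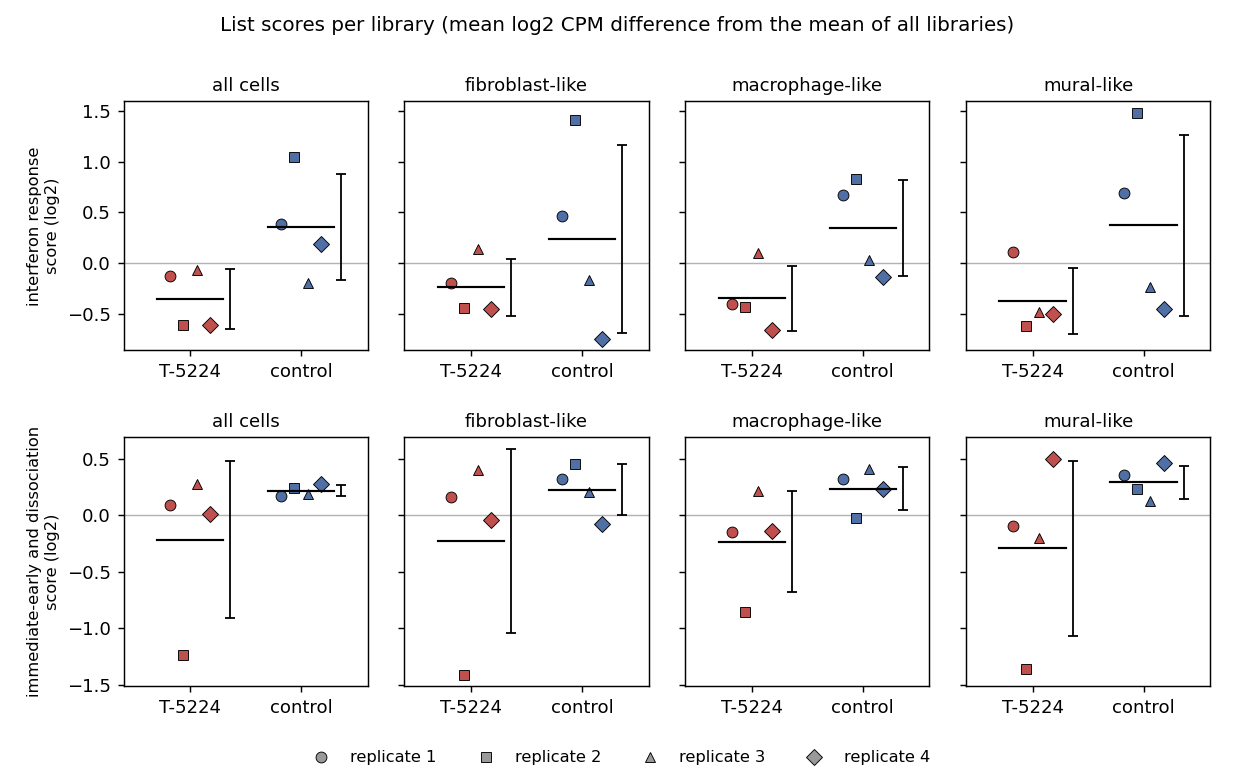
Scores of the interferon response list and of the immediate-early and dissociation list (mean centred log2 CPM of the members) in all cells, fibroblast-like, macrophage-like and mural-like cells, with a point per library, the mean and 1 SD. T-5224 replicate 2 lies lowest in the immediate-early list over all cells at -1.24.

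Of 22558 genes tested over all cells, 0 passed in edgeR, and DESeq2 called 21, all lower. At an unadjusted p under 0.05, 341 were higher and 634 lower (1622 and 1170 without control replicate 4, 91 and 383 without T-5224 replicate 2). Those with the smallest p in edgeR were APOB (-2.04 ± 0.38, 0.127 ± 0.0448 against 0.519 ± 0.177 CPM), LAMA3 (-1.20 ± 0.23), CATSPERB (-1.26 ± 0.24), ANKS4B (-1.80 ± 0.35), and SPINT1 (-1.43 ± 0.28). In these 5 the groups did not overlap, which this choice favours. With the same weight for every class LAMA3 came to -0.44. On the higher side were ssc-mir-214 (1.45 ± 0.35), RIMS2 (0.79 ± 0.19), UNC5C (1.21 ± 0.30), CDKN2A (1.15 ± 0.30) and COX6A2 (0.62 ± 0.17). All 10 had an edgeR adjusted p of 0.734.

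Of the other lists over all cells, 3 more passed with camera and lost their call at an adjusted p of 0.628 with an estimated correlation. Collagens and matrix had 19 of 28 members higher (median 0.19, camera adjusted p = 0.0172), reported AP-1 target genes 12 of 14 lower (-0.37, 0.0192) and heat shock genes 9 of 11 lower (-0.17, 0.0422). The other 16 did not pass (medians from -0.51 for haemoglobin to 0.15 for MHC class II, camera adjusted p from 0.055 to 0.92), among them MAPK feedback (-0.30), TGF-beta ligands and response (-0.22) and matrix proteases (-0.08). Among markers of cell types, those of epithelium (8 of 9 lower, median -1.63, camera adjusted p = 9.66e-08, 4 lower adjusted over the list alone), endothelium (13 of 13 lower, -0.89, 3.05e-05), mesothelium (7 of 9 lower, -0.90, 3.05e-05), lymphatic endothelium (7 of 7 lower, -0.57, 0.00445) and mural cells (11 of 12 lower, -0.47, 0.0421) fell. Those of fibroblasts rose (11 of 12 higher, 0.36, 0.00445). With an estimated correlation these 6 had adjusted p = 0.238 to 0.631. Vessel and mural falls may rest on control replicate 2, richest in those cells. The other 11 marker lists did not pass (medians from -0.54 for adipocytes to 0.44 for plasma cells). In mast cell markers the test pointed down, in neutrophil markers up, and in macrophage markers the mean (0.07) and the test pointed up, each against the median.

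In fibroblast-like cells, collagen genes did not move as a group (16 of 28 higher, median 0.06, camera adjusted p = 0.44). Lists of AP-1 subunits, immediate-early genes, cytokines, interferon and angiogenesis fell with camera. AP-1 subunits had 11 of 11 members lower (median -0.27, camera adjusted p = 0.025), led by JDP2 (-0.35 ± 0.22) and FOSL1 (-0.56 ± 0.36). The immediate-early list had 19 of 21 lower (-0.38, 0.000442), with EGR3 at -1.08 ± 0.55 and IER5 at -0.63 ± 0.38. These and the next 4 lists had adjusted p = 0.788 with an estimated correlation, and 0 of their members passed over all genes in edgeR or adjusted over the list alone. Cytokines had 12 of 14 lower (-0.48, 0.000431), with LIF at 1.23 ± 0.515 against 4.32 ± 3.6 CPM (SD, n = 4; -1.80 ± 0.58, SE) and OSM at -0.65 ± 0.30. Interferon genes had 17 of 21 lower (-0.60, 0.000431), with RSAD2 at -3.08 ± 1.00 and IFI6 at -1.59 ± 0.60 (443 ± 133 against 1335 ± 1018 CPM). Angiogenesis had 9 of 12 lower (-0.40, 0.0287), with VEGFA at -0.87 ± 0.37 and PGF at -1.49 ± 0.68. Ribosomal genes rose with 62 of 69 higher (0.22, 5.69e-07), with RPS19BP1 at 0.35 ± 0.20 and RPL4 at 0.32 ± 0.19. Without low-ribosomal clusters, chosen after seeing the data, the ribosomal median turned to -0.18 (camera adjusted p = 1.63e-09).

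Of 20884 genes in fibroblast-like cells 0 passed in edgeR, and DESeq2 called 1, CENPE. At an unadjusted p under 0.05, 148 were higher and 531 lower (1177 and 1036 without control replicate 4, 67 and 272 without T-5224 replicate 2). CENPE stood at 3.8 ± 0.446 CPM in T-5224 and 13.4 ± 5.76 in controls (SD, n = 4; -1.82 ± 0.34, SE) and passed in edgeR only without control replicate 2 (-2.10, adjusted p = 0.00572). It came to -0.22 with Scrublet calls kept, -0.23 at a Leiden resolution of 2 and -0.30 with classes by cell score. KIF20A lay higher (1.16 ± 0.30), as did LHX8 (1.53 ± 0.40), ssc-mir-214 (1.30 ± 0.36), RIMS2 (0.92 ± 0.26) and RAB7B (1.61 ± 0.47). CATSPERB (-1.36 ± 0.29), UNC13C (-1.42 ± 0.35), FABP6 (-2.89 ± 0.74) and CRYM (-1.53 ± 0.40) lay lower (edgeR adjusted p = 0.814 for all 10). JUNB (-0.22 ± 0.38), FOS (-0.08 ± 0.38), FOSB (-0.33 ± 0.48) and FOSL2 (-0.27 ± 0.22) did not pass, and JUNB, FOS and FOSB came to 0.07, 0.22 and 0.01 without T-5224 replicate 2. FOS also turned to 0.020 without control replicate 3. Without low-ribosomal clusters JUN, JUNB, FOS and FOSL2 came to -0.26, -0.57, -0.40 and -0.12, JDP2 to -0.22, EGR3 to -0.57 and OSM to -0.38. With their share as a covariate JUN, FOSL1 and FOSL2 came to -0.12, -0.34 and -0.048, EGR3 to -0.46 and LIF to -1.20. With the replicate block JUN, JUNB, FOS and FOSB came to -0.17, -0.38, -0.25 and -0.56 and RSAD2 to -1.74. With classes by cell score JUN, JUNB, FOS and JDP2 came to -0.15, -0.39, -0.28 and -0.23, EGR3 to -0.71, PGF to -0.91 and RIMS2 to 0.57.

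The lowest immediate-early, AP-1 and cytokine scores in fibroblast-like cells were those of T-5224 replicate 2 (-1.42, -1.21 and -1.43), and control replicate 2, lowest in depth and highest in mitochondrial share, had the highest interferon score (1.41). Without control replicate 2 RSAD2 came to -1.09, IFI6 to -1.05, LIF to -1.12, PGF to -0.72 and EGR3 to -0.61, and without T-5224 replicate 2 IER5 and JDP2 came to -0.33 and -0.17. Clusters 5 and 10, named fibroblast-like, drew 65.7% and 76.7% of their cells from control replicate 2. Without T-5224 replicate 2 the medians were -0.06 for immediate-early genes (camera adjusted p = 0.816), -0.02 for AP-1 (0.816), -0.29 for cytokines (0.197) and -0.33 for angiogenesis (0.0616), and 4 lists passed in place of 10. Without control replicate 2 they were -0.11 for interferon (0.522), -0.14 for AP-1 (0.116), -0.19 for angiogenesis (0.218), -0.21 for cytokines, which kept their call, and 0.10 for ribosomal genes (0.0183), and 5 lists passed. AP-1 also lost its call without control replicate 3 (-0.24, 0.0541) and angiogenesis without T-5224 replicate 1 (-0.50, 0.0681). Without T-5224 replicate 3 cytokines, immediate-early genes and AP-1 moved to -0.85, -0.59 and -0.52, without control replicate 4 angiogenesis and ribosomal genes to -0.61 and 0.37, and without control replicate 1 ribosomal genes to 0.11. With the low-ribosomal share as a covariate, chosen after seeing the data, calls were lost by interferon (-0.050, 0.298), AP-1 (-0.20, 0.072), angiogenesis (-0.19, 0.072) and ribosomal genes (0.069, 0.17), with RSAD2 at -0.55 and IFI6 at -0.51, while cytokines and immediate-early genes came to -0.16 and -0.23. With classes by cell score they were lost by ribosomal genes (-0.0041, 0.179) and angiogenesis (-0.20, 0.215), the latter also without low-ribosomal clusters (-0.18, 0.0987) and with the replicate block (-0.35, 0.052). Ribosomal genes came to 0.14 with no cell filter and 0.12 at a Leiden resolution of 2. The other 4 lists that passed were hypoxia and glycolysis (-0.23), mitochondrially encoded genes (-0.41), heat shock (-0.21) and reported AP-1 targets (-0.15), with camera adjusted p from 0.029 to 0.0445 and from 0.788 to 0.816 with an estimated correlation. Epithelial markers passed lower here too (median -0.52, camera adjusted p = 0.0189, adjusted p = 0.272 with an estimated correlation). For proliferation the median was -0.01 and the mean and test pointed up. For resident macrophage, contractile and cytotoxic genes the median was above 0 while the mean and test pointed down. The same held for mast cell markers, and for plasma cell markers the mean alone pointed down.

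In macrophage-like cells, genes of the interferon response, of stress and of cytokine signalling lay lower in T-5224 samples and ribosomal genes higher. The class held different clusters by library, with cluster 17 (LYZ, AREG, F13A1) at 25.7%, 13.5%, 25.1% and 11.4% of its cells in T-5224 replicates 1 to 4 and 6.57%, 3.94%, 8.07% and 13.7% in the controls, and cluster 6 (RBM47, MERTK, STAB1) at 8.90% to 40.4% and 11.9% to 55.8%. The interferon list fell with 17 of 21 members lower (median -0.78, camera adjusted p = 3.18e-12, adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone 15 of its members passed lower and 0 over all genes in edgeR (OAS2, MX2 and IFIT2 in DESeq2), led by OAS2, at 199 ± 24.9 against 420 ± 123 CPM (SD, n = 4; -1.08 ± 0.21, SE), and MX2 (-1.12 ± 0.25). The immediate-early list had 21 of 21 lower (-0.51, 8.57e-08), with PPP1R15A at -0.64 ± 0.23 and IER5 at -0.51 ± 0.19. Cytokines had 13 of 14 lower (-0.67, 2.04e-07), with LIF at -1.31 ± 0.36 and OSM at -0.85 ± 0.33. Heat shock genes had 9 of 11 lower (-0.24, 0.00145) and 2 lower adjusted over the list alone, HSPH1, which DESeq2 called too (-0.69 ± 0.17) and DNAJB1 (-0.75 ± 0.23). Apoptosis regulators had 12 of 15 lower (-0.30, 0.00188), with PMAIP1 (-0.76 ± 0.20) and BCL2L11 (-0.93 ± 0.31). These 4 lists had adjusted p = 0.354 with an estimated correlation. Ribosomal genes rose with 66 of 68 higher (0.30, 3.18e-12, adjusted p = 0.447 with an estimated correlation), with RPL26L1 at 0.32 ± 0.12 and RPL7L1 at 0.37 ± 0.14. Apart from interferon and heat shock, 0 members of these lists passed adjusted over the list alone.

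Of 13710 genes in macrophage-like cells 0 passed in edgeR, 736 were higher and 653 lower at an unadjusted p under 0.05, and DESeq2 called 39, of which 37 were lower. The smallest p among lower genes were those of GPR31 (-1.18 ± 0.20), DNAJB4 (-0.71 ± 0.12, 169 ± 12 against 277 ± 25.5 CPM), PPP1R13B (-0.64 ± 0.11), MOB3C (-0.75 ± 0.14) and TRAF1 (-1.35 ± 0.25). Higher were NDUFA10 (0.69 ± 0.15) and NDUFV1 (0.45 ± 0.11), ALG5 (0.57 ± 0.12), PTRH2 (0.69 ± 0.16) and GP6 (1.49 ± 0.37). All 10 had an edgeR adjusted p of 0.472. Without T-5224 replicate 2, whose immediate-early score of -0.86 and cytokine score of -1.73 were the lowest, 7 lists passed in place of 13, apoptosis regulators came to -0.15 (camera adjusted p = 0.0565) and immediate-early genes to -0.34. Cytokines came to -1.0 without T-5224 replicate 3, and interferon to -0.50 with the low-ribosomal share as a covariate. The other 7 lists that passed were proliferation (17 of 17 higher, 0.22), mitochondrially encoded genes (0.17), reported AP-1 targets (-0.48), TGF-beta (-0.34), YAP/TAZ targets (-0.49), coagulation (-0.57) and angiogenesis (-0.41), with camera adjusted p from 0.00305 to 0.0426 and from 0.354 to 0.57 with an estimated correlation. Beside the proliferation change, cluster 28 of dividing cells held 5.10% of the class in T-5224 and 2.56% in control samples. Collagens had a median of -0.10 with a test pointing up. No marker list passed, and the sign of the median, mean or test differed for lymphatic endothelial, dendritic and adipocyte markers. COL1A1, a fibroblast gene, had UMIs in 81.5% of macrophage-like cells of T-5224 samples and 83.9% of controls at median depths of 8786 and 7529 UMIs, against 99.2% and 99.6% of fibroblast-like cells at 15918 and 15054.

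In endothelial-like cells, of which control replicate 2 gave 463 and the other samples 24 to 68, the interferon list lay lower and ribosomal and matrix lists higher in T-5224 samples. Interferon genes fell with 14 of 14 lower (median -0.85, camera adjusted p = 1.22e-09). Adjusted over the list alone 3 passed lower, with MX2 at -1.32 ± 0.36 and IRF7 at -1.63 ± 0.48. Ribosomal genes rose with 67 of 68 higher (0.40, 4.86e-11) and 0 passing adjusted over the list alone, with RPSA at 0.62 ± 0.32 and RPL27A at 0.58 ± 0.32. Collagens and matrix had 17 of 22 higher (0.61, 0.00374). The 1 member passing adjusted over the list alone was COL3A1, at 1624 ± 1513 against 294 ± 158 CPM (SD, n = 4; 2.45 ± 0.64, SE), beside SPARC at 0.80 ± 0.29. Universal fibroblast genes had 4 of 4 higher (0.61, 0.019) and 0 passing adjusted over the list alone, with COL15A1 at 0.91 ± 0.36 and DPP4 at 0.71 ± 0.32. With an estimated correlation these 4 lists had adjusted p = 0.537 to 0.609. COL1A1 had UMIs in 81.2% and 84.8% and COL3A1 in 88.8% and 84.0% of these cells at median depths of 7817 and 6952 UMIs. Markers of fibroblasts lay higher in these cells (7 of 9, median 1.07, camera adjusted p = 0.013, adjusted p = 0.573 with an estimated correlation).

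Of 7139 genes in endothelial-like cells 0 passed in edgeR or DESeq2. At an unadjusted p under 0.05, 181 were higher and 188 lower (694 and 317 without control replicate 4, 93 and 100 without control replicate 2). With no low-count filter edgeR called 67, with DCC, PLXNA4, SELP, S100A6, LGALS1, STMN1, RARRES2, COL3A1, COL1A1 (1.63), MX2, IRF7 and GNLY (3.60) of those named here, and GNLY also passed without T-5224 replicate 1 (4.10). Lower were SELP (-1.60 ± 0.33, 20.5 ± 6.45 against 64.6 ± 15.6 CPM; adjusted p = 0.453), DCC (-3.48 ± 0.64; 0.453), PLXNA4 (-2.68 ± 0.54; 0.453), IMMP2L (-1.09 ± 0.27; 0.841) and SIK2 (-1.08 ± 0.28; 0.841). Higher were S100A6 (1.29 ± 0.27; 0.453), LGALS1 (1.52 ± 0.33; 0.453), STMN1 (1.56 ± 0.40; 0.841), and RARRES2 (2.20 ± 0.63; 0.841). PLXNA4 turned to 0.45 at a Leiden resolution of 0.5 and to 0.52 with classes by cell score, and came to -0.43 with Scrublet calls kept. At the resolution of 0.5 S100A6 came to 0.33, LGALS1 to 0.26, STMN1 to 0.73, RARRES2 to 0.20, COL3A1 to 0.51, SPARC to 0.40, DPP4 to 0.44, IMMP2L to -0.47 and SIK2 to -0.52. With classes by cell score they came to 0.81, 0.37, 0.86, 0.23, 0.44, 0.38, 0.32, -0.31 and -0.42 in this order, and the ribosomal (0.12, 0.205), matrix (0.14, 0.138) and universal fibroblast lists (0.27, 0.457) lost their calls, as the matrix list did at the resolution of 0.5 (0.18, 0.157), and universal fibroblast genes with no low-count filter (0.30, 0.152) or a stricter cell filter (0.45, 0.0639). The ribosomal median came to 0.13 at the resolution of 0.5 and 0.22 with the stricter cell filter, and the matrix median to 0.37 with Scrublet calls kept. With the low-ribosomal share as a covariate ribosomal genes came to 0.21, interferon to -0.53 and the matrix list to 1.16. The matrix call was lost without T-5224 replicate 1 (0.25, camera adjusted p = 0.704), control replicate 4 (0.54, 0.418) or control replicate 1 (0.52). It was also lost with doublets removed at the same expected rate in every sample, chosen after seeing the data (-0.00, 0.572), where S100A6, LGALS1 and COL3A1 came to 0.75, 0.98 and 1.46. The matrix median came to 1.16 without control replicate 2, lowest in depth and highest in mitochondrial share, where universal fibroblast genes lost theirs (0.47, 0.0511). Without control replicate 2 interferon came to -0.48 and ribosomal genes to 0.23, the latter also to 0.19 without T-5224 replicate 2 and 0.65 without control replicate 4, and 8 lists passed without control replicate 3 in place of 4. AP-1 subunits (median -0.02, mean 0.00) had a test pointing down and contractile genes (-0.07, mean 0.07) one pointing up.

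In T/NK-like cells, genes of cell division and of killing lay higher in T-5224 samples, and interferon, immediate-early and collagen genes lower. The class held different clusters by library, with cluster 19, led by the killing genes GNLY and GZMH, at 19.0%, 43.3%, 45.0% and 24.1% of its cells in T-5224 replicates 1 to 4 and 19.6% to 22.2% in the controls. The proliferation list rose with 16 of 16 higher (median 0.90, camera adjusted p = 4.15e-14). Adjusted over the list alone 8 of its members passed and 0 over all genes in edgeR, with BIRC5 at 36.1 ± 13.6 against 15.5 ± 5.11 CPM (SD, n = 4; 1.17 ± 0.31, SE) and STMN1 at 1.21 ± 0.32. The cytotoxic list rose with 9 of 11 higher (0.51, 0.000397), with GNLY at 1.39 ± 0.45 and GZMB at 0.84 ± 0.34. Ribosomal genes rose with 64 of 68 higher (0.31, 1.76e-09), with RPS27L at 0.59 ± 0.17 and RPL26L1 at 0.49 ± 0.23. Interferon genes fell with 14 of 16 lower (-0.74, 1.91e-06), with ISG15 at -0.95 ± 0.29 and IFIT1 at -0.72 ± 0.24. Immediate-early genes fell with 17 of 19 lower (-0.34, 0.000329), with NR4A1 at -0.62 ± 0.22 and ZFP36 at -0.56 ± 0.20. Collagens and matrix had 21 of 21 lower (-1.28, 1.91e-06), with COL1A1 and COL6A3 both at -1.85. COL1A1 reached 4623 CPM in control replicate 2, lowest in depth and highest in mitochondrial share, against 198 to 832 in the other controls. Without that library the matrix median came to -0.30 (camera adjusted p = 0.376), COL1A1 to -0.48 and COL6A3 to -0.32, and with the low-ribosomal share as a covariate, chosen after seeing the data, the median came to -0.20 (0.38) and COL1A1 and COL6A3 to -0.27 and -0.38. That covariate brought interferon to -0.24, ribosomal genes to 0.16 and cytotoxic genes to 0.32, and the matrix median was -0.80 with the replicate block (COL1A1 -0.92, COL6A3 -1.17) and -0.71 with a stricter cell filter (-1.17 and -1.18). With an estimated correlation these 6 lists had adjusted p = 0.521 to 0.58, and 0 members passed adjusted over the list alone except for proliferation.

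Of 9406 genes in T/NK-like cells 0 passed in edgeR, 546 were higher and 289 lower at an unadjusted p under 0.05, and DESeq2 called 0, while 80 passed with no low-count filter, with COL1A1, COL6A3, ISG15, BIRC5, STMN1 and GNLY of those named here. Higher were CDKN2C (1.11 ± 0.26), MRPL57 (0.82 ± 0.19) and MPV17L2 (1.21 ± 0.30), CTSD (0.59 ± 0.14) and VAMP8 (0.58 ± 0.14). Lower were PDE1B (-1.24 ± 0.25), ZBTB16 (-0.61 ± 0.14, 106 ± 11.2 against 163 ± 15.6 CPM), NRP1 (-0.76 ± 0.20) and SLC16A10 (-0.82 ± 0.21). All 9 had an edgeR adjusted p of 0.547. TGF-beta genes (-0.18, 0.0129) and reported AP-1 targets (-0.31, 0.0352) also passed lower, with adjusted p = 0.521 and 0.57 with an estimated correlation. Among markers, those of fibroblasts (11 of 11 lower, -1.22, 0.000569, adjusted p = 0.416 with an estimated correlation) and endothelium (3 of 4 lower, -0.98, 0.00119, adjusted p = 0.0606 with an estimated correlation and 0.0288 with fry) fell. Those of T/NK cells rose (12 of 19 higher, 0.18, 0.0356, adjusted p = 0.405 with an estimated correlation). COL1A1 had UMIs in 69.6% and 77.6% of these cells at median depths of 3045 and 2597 UMIs. Medians moved by over 1.5 times without control replicate 2 for interferon (-0.39), ribosomal (0.11) and cytotoxic genes (0.33), without control replicate 1 for ribosomal (0.16) and cytotoxic genes (0.32), without control replicate 4 for ribosomal genes (0.54), and without T-5224 replicate 2 for immediate-early genes (-0.18). For angiogenesis, hypoxia and universal fibroblast genes the median was above 0 and the mean and test pointed down.

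In mural-like cells, 16 of 24 lists passed, the most of any comparison, with signalling, cytokine, interferon and glycolysis genes lower and division genes higher. The immediate-early list fell with 19 of 20 lower (median -0.45, camera adjusted p = 4.52e-09, adjusted p = 0.276 with an estimated correlation), with SOCS3 at 143 ± 68.4 against 307 ± 73.5 CPM (SD, n = 4; -1.13 ± 0.36, SE) and NR4A1 at -0.87 ± 0.31. The next 5 lists had adjusted p = 0.244 with an estimated correlation. Interferon genes had 12 of 13 lower (-0.94, 1.52e-07) and 5 lower adjusted over the list alone, with ISG15 at -1.73 ± 0.52 and MX1 at -1.54 ± 0.48. Hypoxia and glycolysis genes had 13 of 14 lower (-0.43, 4.73e-06), with BNIP3 at -0.80 ± 0.24 and ENO1 at -0.57 ± 0.20. Cytokines had 10 of 10 lower (-0.75, 0.000118) and 1 lower adjusted over the list alone, PTGS2 (-1.61 ± 0.46), beside CCL3L1 at -1.11 ± 0.61. MAPK feedback genes had 8 of 9 lower (-0.39, 0.000219), with DUSP4 (-0.73 ± 0.23) and DUSP5 (-0.70 ± 0.33). Proliferation genes rose with 13 of 16 higher (0.49, 1.2e-07) and 3 higher adjusted over the list alone, with BIRC5 at 1.06 ± 0.24 and TPX2 at 0.87 ± 0.26. With Scrublet calls kept the median was -0.00 (camera adjusted p = 0.998) and CCL3L1 turned to 0.23, while PTGS2 came to -0.066, TPX2 to 0.14 and the cytokine median to -0.33 (0.0761). Cytokines also lost their call at a Leiden resolution of 2 (-0.50, 0.0849), and with classes by cell score PTGS2 came to -0.59, DUSP4 to -0.16, BIRC5 to 0.23, TPX2 to 0.41 and the immediate-early, MAPK feedback and proliferation medians to -0.28, -0.20 and 0.26. Interferon came to -0.18, ISG15 to -0.80, MX1 to -0.82 and proliferation to 0.23 with the low-ribosomal share as a covariate. Interferon came to -1.56 with no low-count filter and -1.55 with a stricter one, and cytokines to -0.40 with no filter and -0.43 with doublets at the same rate, where CCL3L1 came to -0.72. For immediate-early, hypoxia and MAPK feedback genes 0 passed adjusted over the list alone.

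Of 10319 genes in mural-like cells 0 passed in edgeR, 185 were higher and 243 lower at an unadjusted p under 0.05, and DESeq2 called 5, all lower. Those with a symbol were RGS2, RGS1, BCL2L11 and KCNE4. RGS2 stood at 49.9 ± 11.5 against 204 ± 96.2 CPM (SD, n = 4; -2.07 ± 0.33, SE; adjusted p = 0.519) and RGS1 at -2.10 ± 0.39 (adjusted p = 0.598). BCL2L11 (-1.17 ± 0.21) and KCNE4 (-1.75 ± 0.33) had adjusted p = 0.598, and IGF2BP3 stood at -1.60 ± 0.35. Higher were KIF20A (1.38 ± 0.29), GPRASP2 (1.15 ± 0.25), CEP126 (0.82 ± 0.19) and ZNF782 (1.58 ± 0.39), and these 5 had adjusted p from 0.882 to 1. At a Leiden resolution of 2 KCNE4 came to -1.15 and GPRASP2 to 0.26, and with Scrublet calls kept IGF2BP3 to -0.74. With classes by cell score RGS2 came to -1.35, IGF2BP3 to -0.58, KIF20A to 0.69, GPRASP2 to 0.27, CEP126 to 0.37 and ZNF782 to 0.70. Control replicate 2, lowest in depth and highest in mitochondrial share, gave 735 of these cells, against 32 to 148 in the other libraries. Without it interferon came to -0.47, with ISG15 at -0.73 and MX1 at -0.80, hypoxia to -0.27, with BNIP3 at -0.47 and ENO1 at -0.37, and proliferation to 0.26. Without T-5224 replicate 2, whose immediate-early score was -1.36 and cytokine score -1.98, immediate-early genes came to -0.18, cytokines to -0.43 and MAPK feedback to -0.20. Immediate-early genes came to -0.77 without T-5224 replicate 4, MAPK feedback to -0.72 without T-5224 replicate 3, and cytokines to -1.16 without T-5224 replicate 1 and -0.42 without control replicate 3. The other 10 lists that passed were AP-1 subunits (9 of 11 lower, -0.39), heat shock (-0.32), matrix proteases (-0.32), reported AP-1 targets (-0.32), apoptosis regulators (-0.25), coagulation (-0.22), ribosomal (-0.06), TGF-beta (-0.26), contractile (-0.35) and collagen genes (-0.17), with camera adjusted p from 0.000219 to 0.0412 and from 0.244 to 0.641 with an estimated correlation. No marker list passed.

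In mesothelial-like cells, heat shock, cytokine and AP-1 target genes lay lower in T-5224 samples and ribosomal genes higher, and all 6 lists described had an adjusted p of 0.762 to 0.803 with an estimated correlation. Heat shock genes fell with 10 of 10 lower (median -0.31, camera adjusted p = 7.08e-05), with HSPH1 at 305 ± 108 against 538 ± 53.4 CPM (SD, n = 4; -0.82 ± 0.27, SE) and BAG3 at -0.59 ± 0.23. Cytokines had 9 of 10 lower (-0.84, 0.000103), with CXCL8 at -1.72 ± 0.70 and PTGS2 at -1.44 ± 0.67. Reported AP-1 target genes, a list that also holds CXCL8, had 10 of 13 lower (-0.38, 0.00213), with VEGFA at -1.12 ± 0.42. Immediate-early genes had 17 of 20 lower (-0.36, 0.000754), with IER5 at -0.90 ± 0.42 and BTG2 at -0.54 ± 0.33. Interferon genes had 16 of 19 lower (-0.71, 0.00234), with MX2 at -2.24 ± 0.88 and ISG15 at -2.0 ± 0.82. Ribosomal genes rose with 61 of 68 higher (0.21, 7.08e-05), with RPS19BP1 at 0.52 ± 0.29 and RPL9 at 0.39 ± 0.34. In these lists 0 members passed over all genes in edgeR and 0 adjusted over the list alone. MHC class II genes also passed, 6 of 6 higher (0.65, 0.00699), and AP-1 subunits, 7 of 9 lower (-0.36, 0.0468), both with adjusted p = 0.762 with an estimated correlation.

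Of 12275 genes in mesothelial-like cells 0 passed in edgeR, and DESeq2 called 2, TSPAN15 (-2.86 ± 0.58) and TMEM45B (-3.63 ± 0.79). At an unadjusted p under 0.05, 84 were higher and 211 lower (380 and 346 without control replicate 4, 78 and 147 without control replicate 2). DNAJA4 (-1.08 ± 0.24), ABTB2 (-0.87 ± 0.20) and VDR (-1.62 ± 0.40) also lay lower. On the higher side were WARS1 (1.21 ± 0.28), CFAP69 (1.75 ± 0.47), DAZAP1 (0.63 ± 0.17), PRDM6 (1.06 ± 0.35) and PIK3CD (1.18 ± 0.39), and all 10 had an edgeR adjusted p of 1. VDR turned to 0.18 with Scrublet calls kept, where CXCL8 came to -0.81, and to 0.0031 with classes by cell score. It came to -0.81 with a stricter cell filter, -0.40 at a Leiden resolution of 2 and -0.26 with doublets at the same rate. TSPAN15 came to -1.27 and -0.52 in the first 2 settings. With classes by cell score WARS1 came to 0.76, PRDM6 to 0.49, DNAJA4 to -0.43, HSPH1 to -0.28, BAG3 to -0.33, VEGFA to -0.68, IER5 to -0.55 and BTG2 to -0.23. Calls were lost by ribosomal genes with classes by cell score (0.029, 0.595), by AP-1 targets with these (-0.34, 0.0535) or with Scrublet calls kept (-0.26, 0.0627), and by interferon with at least 50 cells per sample (-0.72, 0.104). With the low-ribosomal share as a covariate they were lost by interferon (-0.063, 0.726) and immediate-early genes (-0.047, 0.24), with MX2 at -0.51, ISG15 at -0.60, BTG2 at -0.18, cytokines at -0.33, PTGS2 at -0.72 and ribosomal genes at 0.12. With doublets at the same rate they were lost by heat shock genes (-0.093, 0.0518) and AP-1 targets (-0.31, 0.151). Heat shock genes came to -0.17 with a stricter cell filter and -0.19 at a Leiden resolution of 2, AP-1 targets to -0.25 with that filter and -0.72 with no low-count filter, cytokines to -0.50 with Scrublet calls kept, and interferon to -0.40 with the replicate block (MX2 -1.13, ISG15 -0.85). With at least 50 cells heat shock genes came to -0.55 and AP-1 targets to -0.63. Control replicate 2, lowest in depth and highest in mitochondrial share, had the highest scores for interferon (1.6), cytokines (1.30), AP-1 targets (1.17) and heat shock genes (0.56), and T-5224 replicate 2 the lowest for cytokines (-1.75) and immediate-early genes (-1.33). Without control replicate 2, 5 lists passed in place of 8, the interferon median was -0.02 with a test pointing up (camera adjusted p = 0.503), and AP-1 targets came to -0.17 (0.398), immediate-early genes to -0.13 (0.333) and cytokines to -0.35 (0.0289). MX2 came to -0.29, ISG15 to -0.13, PTGS2 to -0.50, CXCL8 to -0.83, IER5 to -0.48, BTG2 to -0.24 and VEGFA to -0.67 without that library. Without T-5224 replicate 2 immediate-early genes came to -0.08 (0.862), AP-1 targets to -0.19 (0.0943) and cytokines to -0.41 (0.0482). AP-1 targets lost their call without T-5224 replicate 1 (-0.32), interferon without T-5224 replicate 4 (-0.72), and ribosomal genes without T-5224 replicate 3 (0.08) or control replicate 1 (0.03) or 3 (0.05). Ribosomal genes came to 0.39, 0.34 and 0.46 without T-5224 replicate 1, control replicate 2 and control replicate 4. Heat shock genes came to -0.16 and -0.55 without T-5224 replicates 1 and 4, and AP-1 targets to -0.63, -0.71 and -0.58 without T-5224 replicate 4 and control replicates 3 and 4. For angiogenesis and universal fibroblast genes the median was above 0 while the mean and test pointed down, as for plasma cell markers, and for macrophage markers the mean alone pointed down. No marker list passed.

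The treatment effect in fibroblast-like cells was then compared with that in macrophage-like cells of the same samples. Of 18918 genes 0 passed in edgeR, 313 had a higher and 307 a lower effect in fibroblast-like cells at an unadjusted p under 0.05, and DESeq2 called 3, CENPE (-1.85), NUPR1 (1.83) and ANKRD46 (0.89). With camera 5 lists differed. Mitochondrially encoded genes had 13 of 13 members with a lower effect in fibroblast-like cells (median -0.42, camera adjusted p = 0.00126), ribosomal genes 62 of 69 (-0.10, 0.0149) and proliferation genes 15 of 17 (-0.27, 0.0263). Dividing macrophage-like cells (cluster 28) stayed in their class, while dividing cells with fibroblast genes (cluster 15) were unnamed and left out, so proliferation is compared between a class with and one without its cluster of dividing cells. Interferon genes had 14 of 21 with a higher effect (0.23, 0.0269) and cytotoxic genes 4 of 5 (1.04, 0.0149), 1 of them adjusted over the list alone. The cytotoxic genes are those of lymphocytes, and free RNA was not removed from either class. The T cell gene CD3E had UMIs in 0.761% and 1.14% of fibroblast-like and 0.83% and 1.02% of macrophage-like cells, and GNLY stood at 1.36 and 1.54 CPM in fibroblast-like and 2.76 and 4.20 CPM in macrophage-like cells of T-5224 and control samples. In the other 4 lists 0 passed so. With an estimated correlation the adjusted p was 0.817 for cytotoxic genes and 0.911 for the other 4. All 5 lost calls (camera adjusted p from 0.0593 to 0.644) without single libraries. Mitochondrial genes came to -0.12 without control replicate 2 and cytotoxic genes to 0.97 and 0.27 without T-5224 replicates 1 and 3. Ribosomal genes came to 0.02, -0.10, -0.08 and -0.05 without T-5224 replicates 1 and 3 and control replicates 3 and 4. Proliferation came to -0.33, -0.26 and -0.16 without T-5224 replicates 1, 3 and 4 and to -0.03 (with a test pointing up) without control replicate 2. Interferon came to 0.16, 0.23, 0.18 and -0.01 without T-5224 replicates 1 and 4 and control replicates 1 and 4. Proliferation, interferon and cytotoxic genes also lost their calls with Scrublet calls kept (0.0095, 0.21 and 0.88) and with classes by cell score (0.0053, 0.060 and -0.12), and ribosomal genes at a Leiden resolution of 0.5 (-0.074). Those of proliferation and interferon were lost with no cell filter (-0.23 and 0.16) and at a resolution of 2 (0.050 and 0.17), that of proliferation at 0.5 (-0.17) and that of cytotoxic genes with no low-count filter (0.36). All 3 were lost in 2 settings chosen after seeing the data, doublets at the same rate (-0.097, 0.19 and 0.79) and without low-ribosomal clusters (-0.24, 0.12 and 0.27). Where calls held, cytotoxic genes ran down to 0.27 and ribosomal genes to -0.44. The median and the mean or test differed in sign for MHC class II, MAPK feedback and heat shock genes.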

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

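Fits without single libraries were planned, but reading them as explanations, the test of class shares and the counts of splits for the immediate-early and interferon lists were chosen only after the results were seen. The test of the cell filter was chosen before, and leaving out low-ribosomal clusters is a setting chosen after seeing the data, with its prediction written before its value was seen. In each group of 4 samples the highest and lowest value was compared with the rest by Dixon's test, which by chance marks about 1 in 20 groups. Of 434 groups 45 had a sample apart. Of these 19 were in control replicate 2, 8 in control replicate 3, 6 in T-5224 replicate 2, 4 in T-5224 replicate 1, 3 each in T-5224 replicate 4 and control replicate 4, 2 in T-5224 replicate 3 and 0 in control replicate 1.

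Control replicate 2 stood apart in its shares of mural-like (9.63%, others 0.553% to 1.62%) and endothelial-like cells (6.07%, others 0.630% to 0.960%). It also had the highest median mitochondrial share and lowest median depth of all 8 libraries. It had the highest control level of DLL4 over all cells (14.9 CPM, others up to 1.98), and of JDP2 (80.2), IER5 (75.1) and RSAD2 (23.0) in fibroblast-like cells. In macrophage-like cells LIF (20.0 CPM) and BCL2L11 (121 CPM) were highest there, in T/NK-like cells the matrix genes COL1A1 (4623 CPM) and COL6A3 (372 CPM), and in mural-like cells BNIP3 (174 CPM), ENO1 (510 CPM) and the hypoxia and glycolysis score (0.63). In its mesothelial-like cells VDR (35.7 CPM), CXCL8 (225 CPM), IER5 (79.8 CPM), PTGS2 (677 CPM), MX2 (389 CPM) and ISG15 (773 CPM) lay above the other controls.

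T-5224 replicate 2 lost 26.7% of barcodes at the cell filter and had the lowest T-5224 level of EGR3 over all cells (0.71 CPM, others 1.96 to 2.11). It also had the lowest cytokine scores over all cells (-1.53) and in mural-like cells (-1.98), the lowest immediate-early score in mesothelial-like cells (-1.33), and 0 CPM of TSPAN15 there. T-5224 replicate 1 had more mast-like (1.82%) and fewer B/plasma-like cells (0.320%) than the other T-5224 samples, and more FOSL2 over all cells (50.2 CPM) and in fibroblast-like cells (27.6 CPM). T-5224 replicate 3 had the lowest interferon score in endothelial-like cells (-1.39) and the highest T-5224 level of CXCL8 in mesothelial-like cells (66.8 CPM). T-5224 replicate 4 had less NDUFA10 in macrophage-like cells (54.2 CPM), less LGALS1 in endothelial-like cells (234 CPM) and more VDR in mesothelial-like cells (7.85 CPM) than the other T-5224 samples. Control replicate 3 had less FABP6 (0.072 CPM) and more UNC13C (1.71 CPM) in fibroblast-like cells, and less PMAIP1 in macrophage-like cells (134 CPM). It had more DCC (600.3 CPM) and SIK2 (210 CPM) in endothelial-like cells, more BIRC5 (12.7 CPM) and DUSP5 (193 CPM) in mural-like cells and more DNAJA4 in mesothelial-like cells (32.6 CPM). Control replicate 4 had the highest control proliferation score over all cells (0.19), the highest BIRC5 (14.2 CPM) and the highest cytokine score in macrophage-like cells (0.82).

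The treatment effect differed between fibroblast-like and macrophage-like cells by camera for mitochondrially encoded genes (median -0.42), ribosomal genes (-0.10), proliferation (-0.27), interferon (0.23) and cytotoxic genes (1.04), and none passed with an estimated correlation.

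The immediate-early list score over all cells differed between T-5224 and control by -0.433, and 10 of the 35 splits of the 8 samples gave as small a p, so chance cannot be excluded (-log10 p of 5.46 for the real split and up to 9.29 for others). A shift in class shares is argued against, since the difference in fibroblast-like cells alone was -0.451. The filter step alone is argued against as the source of the low values in T-5224 replicate 2. Its gap to the other T-5224 libraries was -1.37 with the filter and -1.40 with none. After filter and doublet removal it kept 105551621 of 113049483 UMIs, so the barcodes put back could move the gap little. Damage to its cells, or their loss before the filter, was not tested. Without that library -0.0916 of the difference was left, so low values of this 1 library are a candidate explanation for most of it. Genes of this list also respond to tissue handling, and an effect of T-5224 on AP-1 in that sample alone, against handling of that sample, was not tested.

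The interferon score over all cells differed by -0.711, and 2 of the 35 splits gave as small a p, so chance cannot be excluded (-log10 p of 11.7 for the real split and up to 14.7 for others). Cells of low-ribosomal clusters are argued against as its source, since the difference without them was -0.859, where the change from -0.711 had an SE of 0.103. With the share of these clusters per library as a covariate, however, the median change came from -0.81 to -0.40 over all cells. In fibroblast-like cells it came from -0.60 to -0.050, so a trait of libraries that goes with this share stays open. Without control replicate 2, -0.481 (SE 0.226) was left over all cells, -0.538 (SE 0.295) of -0.697 in macrophage-like cells and -0.0857 (SE 0.376) of -0.476 in fibroblast-like cells. The share of that library and a lower interferon response under the T-5224-hydrogel cannot be told apart with these spreads. An infection or another immune stimulus behind single samples was not tested.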

How the results depend on the processing

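Over the alternatives, 165 of 178 gene counts, 71 of 102 list counts, 3463 of 3523 values of named genes, 865 of 964 of lists and 165 of 189 of shares kept their direction and their side of the threshold, or stayed within 1.5 times for counts. For named genes 42 came past the threshold and 18 turned sign, for lists 83 lost a call, 8 gained one and 8 turned, and 24 shares turned. The 3 alternatives chosen after seeing the data are named above. The cause of the changes below was not tested unless given. The setting of at least 50 cells per sample was not possible in endothelial-like and mural-like cells. With 24 to 68 and 32 to 148 such cells in 7 samples, values in these classes rest on few cells.

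Against 0 genes in edgeR, DESeq2 called 21 over all cells, 1 in fibroblast-like, 39 in macrophage-like, 5 in mural-like and 2 in mesothelial-like cells, and 3 for the interaction. With no low-count filter edgeR called 67 in endothelial-like, 80 in T/NK-like and 5 in mural-like cells (KCNE4, RGS2, RGS1 and 2 without a symbol) and 1 for the interaction (CENPE), and with the low-ribosomal share as a covariate 1 in mural-like cells (A2M). Genes outside the rule for named genes were chosen after their values were seen. Leaving out single libraries gave 0 to 1 genes in fibroblast-like and in endothelial-like cells.

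With an estimated correlation 0 lists passed in each of the 8 comparisons, and 0 with fry. Without low-ribosomal clusters 14 lists passed over all cells and 3 for the interaction, and with the low-ribosomal share as a covariate 3 in fibroblast-like and 7 in endothelial-like cells. Leaving out single libraries gave 5 to 14 lists over all cells, 4 to 11 in fibroblast-like, 7 to 16 in macrophage-like, 3 to 8 in endothelial-like and 5 to 10 in mesothelial-like cells, and 1 to 7 for the interaction.

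Ribosomal genes in fibroblast-like cells turned to -0.0041 with classes by cell score and to -0.185 without low-ribosomal clusters, where RPS19BP1 (-0.089) and RPL4 (-0.035) turned too. Cell scores left 14.5% of cells with their top 2 classes within 0.1 and gave 61.6% of named cells the same class. Proliferation turned to -0.0037 in mural-like cells and 0.0095 for the interaction with Scrublet calls kept, and to 0.050 for the interaction at a Leiden resolution of 2. PLXNA4 in endothelial-like cells turned to 0.45 at a resolution of 0.5 and 0.52 with classes by cell score, VDR in mesothelial-like cells to 0.18 with Scrublet calls kept and 0.0031 with classes by cell score, and CCL3L1 in mural-like cells to 0.23 with Scrublet calls kept. The macrophage-like share difference turned to 0.362 points with no cell filter. As centred log-ratios the differences turned to 0.314 for macrophage-like, 0.145 for mural-like, 0.517 for dendritic-like, 0.0529 for mast-like and 0.344 for B/plasma-like cells, and within immune cells to 5.71 points for macrophage-like, 0.396 for dendritic-like and 0.249 for B/plasma-like cells, where the denominator changes.

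Over fits without single libraries, medians ran from -0.92 to -0.023 for interferon in mesothelial-like cells, where the test turned, and for the interaction from -0.19 to 0.022 for ribosomal genes and -0.36 to -0.030 for proliferation. Over all cells and in fibroblast-like cells, JUN ran from -0.36 to 0.13 and -0.36 to 0.22, JUNB from -0.46 to 0.0091 and -0.52 to 0.065, FOS from -0.30 to 0.14 and -0.30 to 0.22, and FOSB from -0.69 to 0.013 and -0.80 to 0.0051. Share differences ran from -2.56 to 0.775 points for macrophage-like, -2.55 to 0.479 for mural-like, -0.518 to 0.180 for dendritic-like, -0.490 to 0.0552 for mast-like and -0.142 to 0.0928 for B/plasma-like cells.

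With the replicate number as a replicate block, edgeR called 0 genes in all 7 comparisons and 10, 8, 13, 4, 9, 16 and 8 lists passed over all cells and in fibroblast-like, macrophage-like, endothelial-like, T/NK-like, mural-like and mesothelial-like cells. Deviations of same-numbered samples over all cells correlated at 0.157, -0.0485, -0.0794 and 0.346. Numbers 1 and 4, not 2 and 3, correlated best with their own number, so pairing stays open.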

Other observations

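The tests of the epithelial genes without control replicate 2 and the split counts at an unadjusted p were chosen only after the results were seen. Those of gut wall cells, of mesothelial-like cells and of calls past the threshold were chosen before. Dividing cells with fibroblast genes (cluster 15: TOP2A, CENPF, UBE2C) made up 3.03 ± 1.10% of cells in T-5224 and 1.81 ± 0.534% in control samples (SD, n = 4, exact permutation p = 0.114), and dividing macrophage-like cells (cluster 28) 0.749 ± 0.140% and 0.451 ± 0.288% (exact permutation p = 0.0857). These p-values are not adjusted for the 33 clusters, where only mesothelial-like cluster 12 lies under 0.05.

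Of the 21 genes that DESeq2 called lower over all cells, 17 have a symbol, among them SI, TMPRSS2, MS4A12, EPCAM, CDH1 and KRT20 of gut epithelium, and the epithelial marker score differed by -1.36. Only 83 cells (0.158%) had UMIs of at least 3 epithelial markers, and these held 62.0% of the UMIs of SI, 78.5% of MS4A12, 1.66% of LAMA3 and 6.62% of those of the 14 called genes with a symbol that are not markers (median gene 10.9%, and 0% to 13.6% by library), so a few gut wall cells in the tissue pieces, or their free RNA, stay open as a source. Without mesothelial-like cells, which were fewer in T-5224 samples, -0.468 of the score difference was left, where the change had an SE of 0.403. Without control replicate 2, -1.01 was left, with an SE of 0.388 between libraries. Of the 83 cells 35 lay in the fibroblast-like class, 22 in the mesothelial-like class, 16 in unnamed clusters and 8 in the macrophage-like class, so the shares of the lining, of gut wall cells and of that library cannot be told apart with these spreads. An effect of T-5224 on the lining was not tested apart from these.

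In each comparison the 35 ways to split the 8 samples into 4 and 4 were counted, the real one included. In edgeR the real split called 0 genes in all 8 comparisons, so all 35 splits gave as many. The other splits reached 0 genes over all cells and in fibroblast-like cells, 2 in macrophage-like, endothelial-like and mesothelial-like cells, and 1 in T/NK-like and mural-like cells and for the interaction. The real split passed 16 lists in mural-like cells against at most 15 in others, 1 split of 35 giving as many. That is the fewest possible, and over the 8 list counts chance stays open. The count was 12 lists without T-5224 replicate 2 and 0 with an estimated correlation. For the other list counts chance cannot be excluded, with real and highest other counts of 9 and 20 over all cells (29 splits as large), 10 and 19 in fibroblast-like (21), 13 and 18 in macrophage-like (9), and 4 and 10 in endothelial-like cells (18). The counts were 8 and 13 in T/NK-like (20), 8 and 16 in mesothelial-like cells (22), and 5 and 13 for the interaction (28).

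At an unadjusted p under 0.05 the real split gave 1389 genes in macrophage-like cells against at most 1088 in others. Only 1 split was as large, the fewest possible, and over the 8 comparisons chance stays open. It cannot be excluded elsewhere, with real and highest other counts of 975 and 5058 over all cells (16 splits as large), 679 and 4837 in fibroblast-like (18), and 369 and 1614 in endothelial-like cells (11). The counts were 835 and 1389 in T/NK-like (3), 428 and 727 in mural-like (21), 295 and 2964 in mesothelial-like cells (26), and 620 and 1967 for the interaction (25). Nor can chance be excluded for the 21 genes of DESeq2 over all cells against 2355 (15) and the 39 in macrophage-like cells against 84 (3). The split of T-5224 replicate 1 with control replicates 1 to 3 against the rest gave the highest counts over all cells (5058 and 2355). This pointed to a sample structure that group differences may carry in part. These 4 libraries had the highest shares of low-ribosomal clusters, 31.5% to 61.6% against 12.7% to 25.2% in the others, and the lowest median depths, 5277 to 11330.5 UMIs per cell against 12711.5 to 17744. No label names a batch along this split.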
